A study of Mus musculus with 8 samples.

How the data were processed

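Single-cell RNA sequencing was done on hearts of C57BL/6 mice after myocardial infarction, per the labels. CD31+ endothelial cells and CD45+ leukocytes were enriched and pooled before loading on the 10x Genomics Chromium system with the 3' reagent kit v2, at a target of 8000 cells per library. The 8 libraries fall into 2 genotypes, Ctrl and Tbx1cko, with 1 library of each at days 4, 5, 6 and 7 after infarction. The labels do not say how many animals were pooled per library, in which cells Tbx1 was deleted or which exons were removed. The deposited files hold UMI counts per gene and barcode, with no normalization, for barcodes that had already been called as cells. The submitters' processing notes name Cell Ranger 2.1.0 and the mm10 build. Gene coordinates are those of mm10.

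All values below were computed from the deposited UMI counts. Barcodes with at least 200 detected genes and under 20% mitochondrial UMIs were clustered with scanpy 1.11.5 and igraph 0.11.9. The clustering used 2000 requested variable genes (1998 after mitochondrial, ribosomal and sex-linked genes, Gm42418 and AY036118 were left out), 30 principal components, 20 neighbours and Leiden resolution 1.0. Barcodes at 10% mitochondrial UMIs or more were then dropped. Doublets were scored per library with Scrublet, and the highest-scoring share, set at 0.8% per 1000 barcodes, was removed. A symbol carried by several identifiers was read from the one with most UMIs.

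Clusters were named "X-like" from 22 fixed marker sets, using markers seen in at least 10% of the cluster's cells and a prior of 10 CPM. A cluster stayed unnamed where doublets exceeded 40%, where fewer than 3 markers were detected or where another class led its top genes. T-like cells were clustered again and named from 5 further sets. Macrophage-like and monocyte-like clusters were joined into a monocyte-macrophage-like class, blood endothelial-like and endocardial-like clusters into an endothelial-like class, mature and conventional dendritic sets into a dendritic-like class, and B and plasma sets into a B-like class. This grouping, and a marker set for immature T-like cells (Dntt, Rag1, Rag2, Ptcra, Cd24a, Arpp21, Themis, Cd1d1), were chosen after the cells had been seen. No cluster took the Regulatory T name. The markers Trac, Trbc1, Trbc2 and Trdc were not used here.

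UMI counts were summed per library and class, and a library entered a class from 20 cells. A class was tested where at least 3 days kept both genotypes, which left 8 classes, while Neutrophil-like and T-like cells lacked day 6. The sums were tested with edgeR 4.0.16 (TMM factors, filterByExpr, quasi-likelihood F-test, two-sided) in R 4.3.3. The genotype fit had day as a factor and 3 residual degrees of freedom. The day fit had day as a number and genotype as covariate, with 5 residual degrees of freedom, so its log2 values are slopes per day. A further fit held the interaction of genotype with day. Adjusted p-values are Benjamini-Hochberg values within a class, with a threshold of 0.05. DESeq2 1.42.0 was run on the same sums and designs. A p-value here measures the spread between these libraries, of which there is 1 per genotype and day, and the labels do not say that they came from separate experiments.

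The libraries of a day share a replicate number and a collection day per the labels. Whether they deviate together was checked from their deviations from the genotype means. The correlations between the paired libraries of days 4, 5, 6 and 7 were 0.784, 0.584, 0.826 and 0.700 in endothelial-like cells and 0.814, 0.689, 0.820 and 0.781 in monocyte-macrophage-like cells. The highest correlation with a library of another day was 0.274. Day was therefore kept as a block in the genotype fits. The day fit has no such term and takes the libraries of a day as independent. Its p-values, and those of the day tests of lists and shares, may therefore be too small. The interaction fit has no day block either, and its p-values may be too large.

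The 26 gene lists were Lymphatic identity, Endothelial leukocyte adhesion, Chemokines, MHC class I presentation, MHC class II presentation, Type I interferon response, Interferon gamma response, Inflammatory activation, Reparative macrophage, T cell cytotoxicity, Regulatory T program, Mature dendritic program, Angiogenesis and Notch, Mesenchymal and matrix, Cell cycle, Glycolysis and hypoxia, Oxidative phosphorylation, Fatty acid handling, Dissociation and early response, Mitochondrially encoded, Female-specific, Y-linked, and transcripts of erythroid, cardiomyocyte, neutrophil and fibroblast cells. Each list with at least 3 tested members was tested with limma 3.58.1 by camera at a preset correlation of 0.01, with adjustment over all lists and classes. Camera with an estimated correlation and fry were run beside it. The Female-specific list never had 3 tested members.

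Class shares were tested with edgeR on cell numbers over all leukocyte-like or all endothelial-like cells, since the ratio of the sorted populations was set at pooling. An exact two-sided permutation test swapping genotype within days has 16 arrangements and cannot go below p = 0.125. Intervals are 95% exact Poisson or binomial (Clopper-Pearson) intervals and cover counting error only, and a count of 0 was taken to allow 3. The limits of the genes around Myt1l are instead 95% normal approximations from the edgeR log2 change and SE.

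The depth was 25694848 to 118706060 UMIs per library. The genotype and day gene tests were run on simulated data drawn from the real means and library sizes with 200 changed genes. The list tests were run on such data with lists of 20 genes shifted by a log2 of 0.5. Genes were drawn independently there, so correlation within lists was not simulated. The class share test was run on made-up class sizes with 1 changed class, and the interaction and T subset tests were not simulated. For genotype, edgeR recovered 87% of genes changed by a log2 of 1 and 98% of those changed by 2 among 12810 genes of monocyte-macrophage-like cells, and 11.9% of its calls were unchanged genes. In endothelial-like cells it recovered 85.7% and 100% of the 98 and 100 genes changed by those sizes among 12605 genes, with 10.2% of calls unchanged, and in B-like cells 51.5% and 99.0% among 4501 genes, with 5.23% of calls unchanged. For day, it recovered 54.5% of slopes of 0.5 and 93% of slopes of 1 in monocyte-macrophage-like cells (12803 genes), 38.8% and 93.9% in endothelial-like cells (12577 genes), and 53.3% and 100% in B-like cells (4461 genes). Each library was drawn independently, without the deviation shared by the libraries of a day. The day values therefore do not measure recovery in these data. The genotype values hold for data with 200 changed genes, where the Benjamini-Hochberg threshold is less strict than where few genes pass. In the real dendritic-like cells Klf2, at an unadjusted edgeR p of 1.04e-05, did not pass (adjusted p = 0.0771). The genotype values may therefore overstate recovery in these data. The share test recovered 79% of simulated genotype changes of log2 2 over 9 classes, with 18.6% of calls unchanged, and 96% of day slopes of 1, with 15.0% unchanged. Those class sizes and their spread were set by hand, and the largest class was left out of the unchanged calls. These values therefore do not measure the test on the real shares.

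Genes are named by a rule. Per class, these were the 5 passing genes with the largest change in each direction, a mean of at least 20 CPM and one sign on every day (for day, in both genotypes), leaving out ribosomal, mitochondrial and sex-linked genes. Where fewer than 3 genes qualified, the 3 with the smallest p and at least 20 CPM are named as values that did not pass. Up to 4 members of each passing list, chosen by p, may be named; the ones printed were picked from these after their values were seen. Tbx1, Prox1, Lyve1, Flt4, Ccl21a, Icam1, Vcam1 and Pdpn are always given for genotype in lymphatic endothelial-like cells, and Ccl21a, Icam1 and Vcam1 for genotype and day in endothelial-like cells. Myt1l, Cd276 and Mt3 fall outside the rule and were named after their values were seen. A gene that the rule names in 2 classes is not reported here.

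Groups, tests, lists, the 22 and 5 marker sets, the naming rule for genes and the alternatives in the next sentence were chosen before the data were examined. The joining of clusters into classes and the immature T-like marker set, on which the immature T-like shares rest, were not. The alternatives were DESeq2, RLE factors, no expression filter, doublets kept, stricter cells (at least 500 genes and under 5% mitochondrial UMIs), a minimum of 50 cells, each day left out, no day term, day as a factor, each genotype alone, Leiden resolution 2.0 and another denominator. Added after seeing the data were cells up to 20% mitochondrial UMIs, female-called cells only (a UMI of Xist and none of Ddx3y, Eif2s3y, Kdm5d or Uty), shares without immature T-like cells, a minimum of 15 cells for lymphatic endothelial-like cells, and Tbx1 with each day left out.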

Results

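Hearts of control (Ctrl) and Tbx1cko mice were profiled by droplet single-cell RNA sequencing at days 4, 5, 6 and 7 after myocardial infarction, with 1 library per genotype and day and 4 libraries per genotype. Tbx1 encodes a T-box transcription factor, and the submitters expected genotype differences to be greatest in the days in which Tbx1 comes back on after injury. The 8 libraries held 64562 barcodes and 600533178 UMIs. The Ctrl libraries of days 4, 5, 6 and 7 held 7958, 8915, 4005 and 6964 barcodes with 118706060, 69684348, 25694848 and 68135096 UMIs. The Tbx1cko libraries of the same days held 7320, 13598, 6282 and 9520 barcodes with 108243436, 80964079, 54011134 and 75094177 UMIs, against a stated target of 8000 cells. After removal of doublets and of barcodes rich in mitochondrial UMIs, 55433 cells were kept and 53672 were named.

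The named cells were mainly of the 2 sorted lineages. There were 17252 endothelial-like and 240 lymphatic endothelial-like cells, 27611 monocyte-macrophage-like cells, 1141 dendritic-like, 1056 neutrophil-like, 555 T-like, 523 B-like, 141 NK-like, 94 plasmacytoid dendritic-like and 33 innate lymphoid type 2-like cells. Cells outside the sort were 1943 mural-like and 832 fibroblast-like cells, and in Ctrl and Tbx1cko 920 and 681 erythroid-like, 73 and 53 cardiomyocyte-like and 32 and 11 Schwann-like cells. A further 481 cells were named immature T-like by genes of developing T cells (Dntt, Rag1, Rag2 and Ptcra among them), a marker list added after the files were seen. The innate lymphoid type 2-like cluster also held Cpa3 and Fcer1a, which mark mast cells and basophils. A cluster led by Ctsk, Mmp9, Acp5, Mt3 and Atp6v0d2, genes of bone-resorbing cells, stayed unnamed.

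Libraries of some days stood apart. The day 6 libraries filled their own clusters, led by AY036118, Gm42418 and processed pseudogenes, with 85.1% of the day 6 endothelial-like cells in 1 cluster. Monocyte-macrophage-like clusters 18 and 15 were made up mostly of day 6 cells (97.8% and 91.4%) and differed by genotype. Over all days cluster 18 held 1031 Ctrl and 75 Tbx1cko cells, and cluster 15 held 92 Ctrl and 1535 Tbx1cko cells. Gm42418 and AY036118 together took 1.17% of UMIs in the Ctrl and 0.601% in the Tbx1cko library of day 6, against 0.0590% to 0.131% on the other days. Cells with Xist and no Y-linked UMI were 0% of both day 4 libraries, 28.1% and 27.8% at day 5, 96.8% and 85.8% at day 6, and 93% and 67.5% at day 7 (Ctrl and Tbx1cko). In the Tbx1cko library of day 7 the median mitochondrial share was 8.38%, and 36.9% of its barcodes were dropped at the 10% limit.

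Tbx1 transcripts were fewer in the Tbx1cko libraries on all 4 days and lay mostly in lymphatic endothelial-like cells, with 213 of the 245 UMIs of all Ctrl cells and 68 of the 86 of all Tbx1cko cells. Tbx1 (ENSMUSG00000009097, chromosome 16, 18580979 to 18590671, minus strand) had 225 UMIs in the endothelial-like and lymphatic endothelial-like cells of Ctrl and 70 in Tbx1cko. Its level was 2.57 ± 1.32 CPM of the UMIs of these cells in Ctrl and 0.831 ± 0.666 in Tbx1cko (SD, n = 4), and the ratio over all days was 0.350 (95% interval 0.263 to 0.459). The ratio was 0.531 at day 4, 0.168 at day 5, 0.177 at day 6 (5 against 1 UMI, interval 0.00375 to 1.58) and 0.311 at day 7. The edgeR log2 difference was -1.58 (SE 0.31), with an unadjusted p of 0.000686 and an adjusted p of 0.9997. The exact two-sided permutation test gave p = 0.125, the smallest it can give. In lymphatic endothelial-like cells the ratio was 0.553 (0.414 to 0.729), against 0.862 (0.736 to 1.01) for Prox1, which sets lymphatic identity. By day, these ratios were 0.710, 0.487, 0.128 and 0.460 for Tbx1 and 0.948, 0.615, 0.712 and 0.657 for Prox1. In the joined endothelial classes the Prox1 ratio was 0.706 (0.622 to 0.801). A 3' tag may lie outside the deleted exons, which the labels do not give, so the level does not measure how complete the deletion was.

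**Figure D1:**
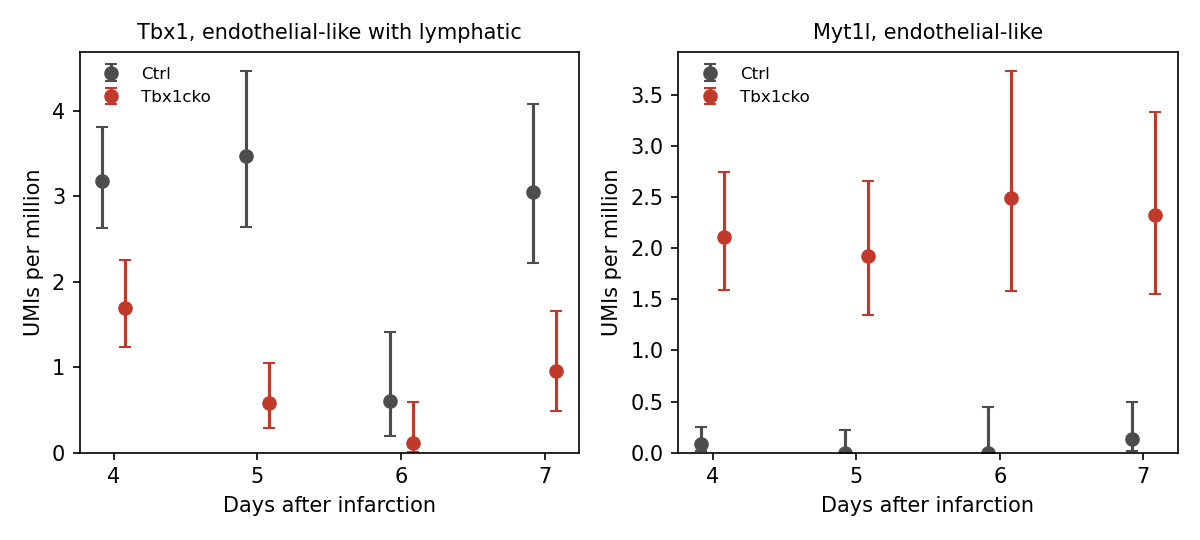
UMIs as CPM in endothelial-like cells (Myt1l) and in endothelial-like plus lymphatic endothelial-like cells (Tbx1) against day after infarction, with 1 point per library, Ctrl in grey and Tbx1cko in red, and exact Poisson 95% intervals as bars. Tbx1 was lower in Tbx1cko on each day (2.57 against 0.831 on average) and Myt1l lay between 1.92 and 2.49 in Tbx1cko and at 0.138 or below in Ctrl.

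The first comparison asked how Tbx1cko and Ctrl differed at the level of genes within each cell class, with the 4 days as blocks. A single gene passed in the 8 classes together, in endothelial-like cells. At an unadjusted p under 0.05 there were 1889, and DESeq2 called 11. In each class the genes at an unadjusted p under 0.05 were fewer than the share of 0.05 that unchanged genes would give. They ran from 142 of 7426 genes tested in neutrophil-like cells to 341 of 7426 in dendritic-like cells. The counts at that threshold given by class below are therefore no sign of changes short of the adjusted threshold. Leaving out a day moved the edgeR count to 6 without day 4, 16 without day 5, 8 without day 6 and 8 without day 7. The fit without the day block called 0, with 332 at an unadjusted p under 0.05. Of the 185 list tests, 76 passed camera at the preset correlation, 38 in each direction. With an estimated correlation 0 passed (11 at an unadjusted p under 0.05, smallest adjusted p = 0.738), and with fry 0 passed (7 at an unadjusted p under 0.05, smallest adjusted p = 0.773).

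In endothelial-like cells the 1 passing gene was Myt1l, and Interferon gamma response and Cell cycle were higher as lists at the preset correlation (adjusted p = 0.738 each with an estimated correlation). Myt1l (ENSMUSG00000061911, chromosome 12, 29528384 to 29923213), a zinc finger transcription factor of neurons, rose by a log2 of 4.91 (SE 0.46, edgeR adjusted p = 0.0277), from 0.0558 ± 0.0675 to 2.23 ± 0.273 CPM (SD, n = 4). It was higher on 4 of 4 days, and the call held without day 6. It was lost without day 4, day 5 or day 7, at a log2 of 5.26, 4.61 and 5.28 (edgeR adjusted p = 0.205, 0.0648 and 0.163), in female-called cells (4.98, adjusted p = 0.0598) and without the day block (4.95, adjusted p = 0.0551). It rests on 144 UMIs in Tbx1cko against 5 in Ctrl. Among Interferon gamma response genes 19 of 20 were higher (median 0.27), with 0 passing over all genes tested or adjusted over the list alone. Examples were the chemokines Cxcl9 (0.49, SE 0.14) and Cxcl10 (0.41, SE 0.11), which draw CXCR3-bearing T cells. Among the Tbx1cko libraries that of day 7, with a median mitochondrial share of 8.38%, stood apart for Cxcl9 (310.4 CPM against 97.3 for the next Tbx1cko library) and H2-Q6 (294 against 137). The Ctrl library of day 7 had H2-Q6 at 177 CPM, above the other Ctrl libraries. Cxcl9 was at 0.31 without day 7, and Cxcl10 had 80.6 CPM in Tbx1cko and 79.4 in Ctrl at day 6. Cell cycle genes were higher for 28 of 30 (median 0.30), such as the spindle genes Nusap1 (0.48, SE 0.15) and Tpx2 (0.42, SE 0.16), with 0 passing over all genes tested or adjusted over the list alone. Both lists passed camera and had adjusted p = 0.738 with an estimated correlation. Over all days, cluster 14, with Cenpf, Cdk1 and Top2a among its leading genes, was 8.93% of endothelial-like cells in Ctrl and 11.6% in Tbx1cko. A change of expression within the class was not separated from that shift. MHC class I presentation (16 of 19 higher, median 0.14, adjusted p = 0.738 with an estimated correlation) and MHC class II presentation (11 of 14 higher, median 0.25, adjusted p = 0.775 with an estimated correlation) also passed camera, again with 0 members adjusted over the list alone. H2-Q6 and H2-Q7, class I genes at 0.41 each (SE 0.10 and 0.13), are near-identical copies whose reads may be split and are uncertain.

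Col3a1 (ENSMUSG00000026043, chromosome 1), a fibrillar collagen chain, had 28.8 ± 8.14 CPM in Ctrl and 19.3 ± 6.69 in Tbx1cko (n = 4; log2 -0.60, SE 0.10, edgeR adjusted p = 0.979), and Col1a1 had a log2 of -0.81 (SE 0.19). Fibroblast transcripts were lower for 11 of 12 (median -0.31), with 4 passing when adjusted over the list alone and 0 over all genes tested, and Mesenchymal and matrix genes for 19 of 25 (median -0.09), with 3 and 0. Both had adjusted p = 0.738 with an estimated correlation. Fibroblast-like cells themselves made up 1.95 ± 1.25% of the kept cells in Ctrl and 1.02 ± 0.509% in Tbx1cko (n = 4). At day 6 they were 0.695% in Ctrl and 1.004% in Tbx1cko, with Col3a1 at 38.7 and 27.4 CPM in endothelial-like cells. Erythroid transcripts were lower for 5 of 5 (median -0.32, adjusted p = 0.738 with an estimated correlation), and erythroid-like cells were 3.11 ± 2.34% in Ctrl and 2.38 ± 2.27% in Tbx1cko, though higher in Tbx1cko at day 6 (0.173% against 0.0869%) and day 7 (5.54% against 4.06%). The leukocyte adhesion receptors Icam1 (0.13, SE 0.09) and Vcam1 (0.18, SE 0.13) and the lymphatic chemokine Ccl21a (-0.66, SE 0.19; its reads are shared with near-identical copies) did not pass.

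In monocyte-macrophage-like cells lists passed camera in both directions, with adjusted p = 0.738 or above with an estimated correlation, and 0 genes were past the edgeR threshold (419 at an unadjusted p under 0.05; 9 by DESeq2). At day 6, cluster 18 held most of the Ctrl and cluster 15 most of the Tbx1cko cells that lay in these 2 clusters. Over all days, cluster 2, with Cd74 and H2-Eb1 among its leading genes, was 13.9% of the class in Ctrl and 17.9% in Tbx1cko. A change of expression within the class was not separated from such shifts. MHC class II presentation was higher for 13 of 14 (median 0.30), with Cd74, the invariant chain, at 0.41 (SE 0.15) and H2-Eb1, a class II beta chain, at 0.36 (SE 0.15). Chemokines were higher for 17 of 24 (median 0.19), among them Ccl17, a ligand of CCR4 (1.19, SE 0.26, from 1.48 ± 0.591 to 3.81 ± 2.11 CPM, n = 4; 2.15 in female-called cells), and Cxcl1, a neutrophil attractant (0.41, SE 0.17). For both, 0 members passed over all genes or adjusted over the list alone, and adjusted p = 0.738 with an estimated correlation. Inflammatory activation was higher for 21 of 23 (median 0.15), with Tnip3, an NF-kappaB feedback gene, at 0.35 (SE 0.12), 0 adjusted over the list alone, and adjusted p = 0.767 with an estimated correlation. Interferon gamma response genes were lower for 16 of 19 (median -0.16), with the guanylate-binding gene Gbp7 at -0.27 and the immunity-related GTPase Irgm2 at -0.28, 0 adjusted over the list alone, and adjusted p = 0.738 with an estimated correlation.

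Fibroblast, matrix, angiogenesis and erythroid lists were also lower in monocyte-macrophage-like cells, each with adjusted p = 0.738 with an estimated correlation. Fibroblast transcripts were lower for 12 of 12 (median -0.74), with 11 passing when adjusted over the list alone and 0 over all genes tested, and Mesenchymal and matrix genes for 19 of 24 (median -0.50), with 14 and 0. Mgp, which keeps matrix from calcifying, had 59.3 ± 37.7 CPM in Ctrl and 35.8 ± 19.7 in Tbx1cko (n = 4; -0.69, SE 0.09, edgeR adjusted p = 0.351), and the proteoglycan Bgn had -0.56 (SE 0.09). Angiogenesis and Notch genes were lower for 26 of 26 (median -0.34) and erythroid transcripts for 5 of 5 (median -0.54), with 0 adjusted over either list alone. Cd24a, a surface glycoprotein of immature lymphocytes, was at 0.44 (SE 0.07, adjusted p = 0.651), beside the T cell genes Cd3d, Cd3e, Cd3g, Tcf7 and Satb1 among the DESeq2 calls and immature T-like cells at 0.314% of leukocyte-like cells in Ctrl and 3.80% in Tbx1cko; Ctla2a, a cysteine protease inhibitor, was at -0.39 (SE 0.09).

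In mural-like cells interferon-response and chemokine lists were higher in Tbx1cko at the preset correlation (adjusted p = 0.738 each with an estimated correlation), with 0 genes past the edgeR threshold (276 at an unadjusted p under 0.05; DESeq2 0). Interferon gamma response genes were higher for 16 of 18 (median 0.34), such as the guanylate-binding genes Gbp5 (0.51, SE 0.21) and Gbp3 (0.44, SE 0.17), with 0 adjusted over the list alone. Without day 7 these were at 0.20 and 0.17. Among the Tbx1cko libraries that of day 7 stood apart for both (67.9 CPM against 16.5 for the next Tbx1cko library, and 135 against 47.6). Among the Ctrl libraries that of day 7 stood apart for Gbp5 as well (35.02 CPM against 12.3). Type I interferon response genes were higher for 20 of 24 (median 0.22), with 5 passing when adjusted over the list alone and 0 over all genes tested, led by the antiviral genes Ifit2 (0.79, SE 0.21) and Ifit1 (0.73, SE 0.17). Chemokines were higher for 14 of 19 (median 0.17; 1 adjusted over the list alone, Cxcl1 at 0.61, SE 0.12), and Ccl2, the monocyte attractant, was at 0.40 (SE 0.15). Plac8, a gene of monocytes and plasmacytoid cells, was at 0.80 (SE 0.17; -0.25 in female-called cells and 0.38 with doublets kept), the Y-linked list at a median of 0.68 (3 of 3 higher, adjusted p = 0.738 with an estimated correlation) and erythroid transcripts at 0.58 (5 of 5 higher, adjusted p = 0.738 with an estimated correlation). Male-called cells were 0% of the Ctrl and 11.4% of the Tbx1cko library at day 7.

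In dendritic-like cells Klf2, a flow- and migration-linked transcription factor, was at 606 ± 347 CPM in Ctrl and 368 ± 213 in Tbx1cko (n = 4; -0.71, SE 0.11), lower on 4 of 4 days. It did not pass edgeR (adjusted p = 0.0771) and was called by DESeq2. The edgeR count was 0 with 341 at an unadjusted p under 0.05, and 14 without day 5, 6 without day 6 and 3 without day 7. Endothelial leukocyte adhesion genes were lower for 10 of 12 (median -0.53), with 6 passing when adjusted over the list alone and 0 over all genes tested, including the junction gene Esam (-1.10, SE 0.20, adjusted p = 0.210) and the endothelial and mural gene Mcam (-1.64, SE 0.37). Fibroblast transcripts were lower for 7 of 8 (median -0.88; 6 adjusted over the list alone), with Mgp at -0.77 (SE 0.16), and erythroid transcripts for 4 of 4 (median -2.63; 4 adjusted over the list alone), with the hemoglobin gene Hba-a1, a near-identical copy of Hba-a2 and therefore uncertain, at -2.75 (SE 0.52). These 3 lists had adjusted p = 0.738 with an estimated correlation. Among the Ctrl libraries that of day 6 stood apart for Mcam (51.4 CPM against 14.5 for the next Ctrl library) and Mgp (139 against 44.8). Among the Tbx1cko libraries that of day 6 stood apart for Mgp as well (87.1 CPM against 24.5). With doublets kept, Esam was at -0.69, Mcam at -0.94 and Hba-a1 at -1.27, and in female-called cells Hba-a1 passed at -1.69 (edgeR adjusted p = 0.0476). MHC class II presentation was higher for 11 of 14 (median 0.12, 0 adjusted over the list alone, adjusted p = 0.767 with an estimated correlation), with Cd74 at 0.27 (SE 0.12).

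Neutrophil-like cells, compared at days 4, 5 and 7, had Inflammatory activation higher and Type I interferon response lower at the preset correlation (adjusted p = 0.738 each with an estimated correlation), with 0 genes past the edgeR threshold (142 at an unadjusted p under 0.05; DESeq2 0; 5 without day 4). Inflammatory activation was higher for 20 of 22 (median 0.26), with 2 passing when adjusted over the list alone and 0 over all genes tested. Il1a, an alarm cytokine, had 65.8 ± 33.3 CPM in Ctrl and 213 ± 202 in Tbx1cko (n = 3; 1.46, SE 0.31, edgeR adjusted p = 1). The chemokine Ccl4 was at 0.73 (SE 0.19), and the hypoxia genes Ero1l (1.15, SE 0.33) and Hilpda (0.86, SE 0.26) stood among Glycolysis and hypoxia genes, 16 of 23 higher (median 0.12). Without day 4, Il1a was at 0.85, Ero1l at 0.48 and Hilpda at 0.50. Type I interferon response genes were lower for 23 of 26 (median -0.30), with the regulator Irf7 at -0.68 (SE 0.18) and the nucleic acid sensor Zbp1 at -0.50 (SE 0.20); 0 passed when adjusted over either of these lists alone. All 3 lists had adjusted p = 0.738 with an estimated correlation. Hbb-bt, a hemoglobin gene with near-identical copies, was at -2.09 (SE 0.45) beside erythroid transcripts lower for 4 of 4 (median -2.27; 4 adjusted over the list alone, adjusted p = 0.738 with an estimated correlation), and the processed pseudogene Gm10076 at 0.93 (SE 0.21) is uncertain.

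In fibroblast-like cells Ptgs2, the inducible prostaglandin synthase, was at 233 ± 29.9 CPM in Ctrl and 150 ± 24.1 in Tbx1cko (n = 4; -0.64, SE 0.15), lower on 4 of 4 days with an edgeR adjusted p of 1. The edgeR count was 0 (198 at an unadjusted p under 0.05; DESeq2 0; 5 without day 7). Adhesion genes were higher for 10 of 13 (median 0.29, 0 adjusted over the list alone, adjusted p = 0.738 with an estimated correlation), with the junctional molecule F11r at 0.89 (SE 0.27) and Icam1 at 0.45 (SE 0.18). Hbb-bt (-2.15, SE 0.47) and Hba-a2 (-2.11, SE 0.54), copies that are uncertain, stood among erythroid transcripts lower for 4 of 4 (median -2.07; 4 adjusted over the list alone, adjusted p = 0.738 with an estimated correlation). In B-like cells 2810417H13Rik was at 1.69 (SE 0.35), Hist1h2ap at 1.51 (SE 0.35) and Vpreb3, a surrogate light chain partner, at -1.07 (SE 0.25), with an edgeR adjusted p of 0.9999 each. Cell cycle did not pass camera there (7 of 9 higher, median 0.14, adjusted p = 0.367). In T-like cells at days 4, 5 and 7 Ctla4, an inhibitory receptor, was at -1.03 (SE 0.22; 188 ± 25.8 CPM in Ctrl and 84.9 ± 36.3 in Tbx1cko, n = 3), the CD8 alpha chain Cd8a at 1.05 (SE 0.26) and Gm10076 at 0.80 (SE 0.20), with an edgeR adjusted p of 0.996 each. In B-like and T-like cells 0 genes passed edgeR (115 and 105 at an unadjusted p under 0.05; DESeq2 0 in both; T-like 2 without day 5).

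Over the classes, the lists that passed camera for genotype most often were erythroid transcripts (7 of 8 classes, 6 of them lower), MHC class II presentation (5, all higher) and Mitochondrially encoded (5, all higher), with the median mitochondrial share of Tbx1cko at day 7 at 8.38%. Lists passing in 4 classes were Interferon gamma response (2 higher, 2 lower), Type I interferon response (1 higher, 3 lower), adhesion (1 higher, 3 lower), Reparative macrophage (1 higher, 3 lower), Glycolysis and hypoxia (2 higher, 2 lower), cardiomyocyte transcripts (1 higher, 3 lower) and fibroblast transcripts (4 lower). Those passing in 3 were MHC class I presentation (2 higher, 1 lower), Chemokines (3 higher), Inflammatory activation (3 higher), Angiogenesis and Notch (3 lower), Cell cycle (2 higher, 1 lower), Oxidative phosphorylation (3 higher), and Dissociation and early response (2 higher, 1 lower). Mesenchymal and matrix (2 lower), Fatty acid handling (2 lower) and neutrophil transcripts (1 higher, 1 lower) passed in 2, and Lymphatic identity (lower), T cell cytotoxicity, Mature dendritic program and Y-linked (each higher) in 1. The Regulatory T program passed in 0 of 6 classes by camera. Every one of these calls was lost with an estimated correlation (adjusted p = 0.738 or above).

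Lymphatic endothelial-like cells, 225 over days 4, 5 and 7, had no identity gene that passed between genotypes. Tbx1 was at -0.79 (SE 0.25) on these days, Prox1 at -0.38 (SE 0.21), the mucin-type glycoprotein Pdpn at -0.28 (SE 0.21), Ccl21a at -0.23 (SE 0.20), the VEGF-C receptor Flt4 at -0.19 (SE 0.26), the hyaluronan receptor Lyve1 at 0.02 (SE 0.31) and Icam1 at 0.32 (SE 0.29). Vcam1 did not reach the expression filter. For genotype, edgeR called 0 of 4082 genes (138 at an unadjusted p under 0.05), DESeq2 was not run here, and the minimum of 15 cells was set after seeing the data. For the day slope, edgeR called 117 of these genes, 96 rising and 21 falling, which are not among the counts by class given below.

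The second comparison asked whether cell make-up differed between genotypes. Monocyte-macrophage-like cells were 88.8 ± 8.07% of leukocyte-like cells in Ctrl and 84.3 ± 10.4% in Tbx1cko (n = 4), lower on 4 of 4 days (exact two-sided permutation p = 0.125). With immature T-like cells left out of the denominator, a setting chosen after the data were seen, the share was lower on 3 of 4 days, at 77.7% in Ctrl and 79.0% in Tbx1cko at day 7 (exact two-sided permutation p = 0.375). The log2 difference then went from -0.078 to -0.025. Dendritic-like cells were 3.14 ± 0.191% and 3.67 ± 0.921%, T-like cells 1.97 ± 2.61% and 1.78 ± 1.66%, and neutrophil-like cells 3.23 ± 3.08% and 3.88 ± 3.61%. Immature T-like cells were 0.314 ± 0.627% in Ctrl and 3.80 ± 6.15% in Tbx1cko (log2 3.93, edgeR adjusted p = 0.570). Of endothelial-like cells, blood endothelial-like cells were 95.2 ± 2.12% and 94.9 ± 2.17%, endocardial-like cells 3.34 ± 1.67% and 3.84 ± 1.75%, and lymphatic endothelial-like cells 1.45 ± 1.16% and 1.23 ± 0.893%. edgeR called 0 of 12 classes (1 at an unadjusted p under 0.05), and 1, the immature T-like cells, over a denominator of all cells (4.01, adjusted p = 0.0320). Of T-like cells, CD8 T-like cells were 42.8 ± 19.5% and 46.6 ± 14.9%, CD4 T-like 25.2 ± 8.98% and 26.6 ± 11.2%, naive T-like 25.6 ± 10.6% and 21.0 ± 10.5%, and gamma delta T-like 6.42 ± 5.80% and 5.76 ± 2.68%; edgeR called 0 of 4 subsets (0 at an unadjusted p under 0.05, adjusted p of 0.458 or above).

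The third comparison followed the course from day 4 to day 7 shared by both genotypes. The mix of clusters within a class moved as well. From day 4 to day 7, endothelial-like cluster 4 went from 51.0% to 12.2% of its class and cluster 0 from 18.7% to 51.3%. Monocyte-macrophage-like cluster 3, with Spp1 and Hmox1 among its leading genes, went from 25.4% to 3.78%, and cluster 2, with Cd74 and H2-Eb1, from 7.13% to 31.3%. Cluster 9, with Lyve1 and Mgl2, went from 3.26% to 12.2%, and cluster 13, with Cdca3 and Ube2c, from 9.70% to 3.29%. Several genes named below for their slope in this class thus lead clusters whose share moved the same way. A slope within a class was not separated from such a shift. Across classes, 791 genes had a slope that passed, 620 rising and 171 falling, in a fit that takes the libraries of a day as independent. Of these, 354 were in monocyte-macrophage-like cells, 158 in neutrophil-like, 120 in B-like, 111 in fibroblast-like, 35 in T-like and 11 in dendritic-like cells, and 1 each in endothelial-like and mural-like cells. DESeq2 called 2821. Without day 4 the edgeR count was 373, without day 5 569, without day 6 5403 and without day 7 2749. Sex moved with day: female-called cells went from 0% to 93% and 67.5%. Y-linked genes were lower for 4 of 4 in endothelial-like cells (median slope -1.21, adjusted p = 0.509 with an estimated correlation). Among female-called cells of days 5 to 7, edgeR called 0 genes, with 2048 at an unadjusted p under 0.05. There, 320 of 320 called genes of monocyte-macrophage-like cells that could be tested, selected for their slope, kept their sign, with a median slope in the called direction of 0.50 against 0.54. All cells of days 5 to 7 also gave 0 calls in this class.

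Interferon gamma response and MHC class II presentation were higher with day in monocyte-macrophage-like cells (adjusted p = 0.473 each with an estimated correlation), and Cell cycle was lower (0.446). Of 354 passing genes, 290 rose and 64 fell. Among the risers were Txnip, a thioredoxin-binding brake on glucose uptake (0.92 per day, SE 0.08, edgeR adjusted p = 0.00781), the immediate early gene Egr1 (0.91, SE 0.17), and Lyve1 (0.82, SE 0.12) and Mgl2 (0.81, SE 0.09), both of tissue-resident macrophages. Falling genes were the mitotic genes Cdca3 (-0.66, SE 0.14; -1.05 without day 7) and Ube2c (-0.54, SE 0.11), the heme oxygenase Hmox1 (-0.59, SE 0.08), the adenosine receptor Adora2b (-0.55, SE 0.08) and the platelet-factor chemokine Pf4 (-0.51, SE 0.09). The largest edgeR adjusted p among these 9 was 0.0490. Interferon gamma response genes were higher with day for 19 of 19 (median 0.43), 7 rising over all genes tested and 16 when adjusted over the list alone. They included Iigp1 (0.79, SE 0.07), a GTPase against intracellular pathogens, and the transcription factor Irf1 (0.62, SE 0.08). MHC class II presentation was higher for 14 of 14 (median 0.40; 5 rising over all genes tested, 12 adjusted over the list alone), with H2-Eb1 (0.66, SE 0.08) and Ciita, the class II transactivator (0.58, SE 0.08). Both lists had adjusted p = 0.473 with an estimated correlation.

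Cell cycle genes were lower with day for 29 of 30 in monocyte-macrophage-like cells (median -0.33), with 7 falling over all genes tested and 25 when adjusted over the list alone, such as the S-phase cyclin Ccna2 (-0.57, SE 0.08) and the mitotic kinase Cdk1 (-0.39, SE 0.06). Dissociation and early response genes, which also respond to tissue digestion, were higher for 22 of 27 (median 0.36; 7 rising over all genes tested, 13 adjusted over the list alone), with Ier2 (0.73, SE 0.09) and Jun (0.51, SE 0.09). Both had adjusted p = 0.446 with an estimated correlation. MHC class I presentation was higher for 18 of 19 (median 0.19; 2 over all genes tested, 5 higher and 1 lower adjusted over the list alone; adjusted p = 0.596 with an estimated correlation), led by the copies H2-Q6 (0.72) and H2-Q7 (0.60), which are uncertain. Mitochondrially encoded genes were higher for 13 of 13 (median 0.26; 0 adjusted over the list alone, adjusted p = 0.617 with an estimated correlation). edgeR called 0 genes in this class without day 4 and 0 without day 5 (1116 and 2003 at an unadjusted p under 0.05), 2309 without day 6 and 1024 without day 7. Without day 4 or day 5, 354 of 354 called genes, selected for their slope, kept their sign, with median slopes in the called direction of 0.53 and 0.54 against 0.54. Of the called genes tested, 335 of 335 passed without day 6 and 114 of 332 without day 7.

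**Figure D2:**
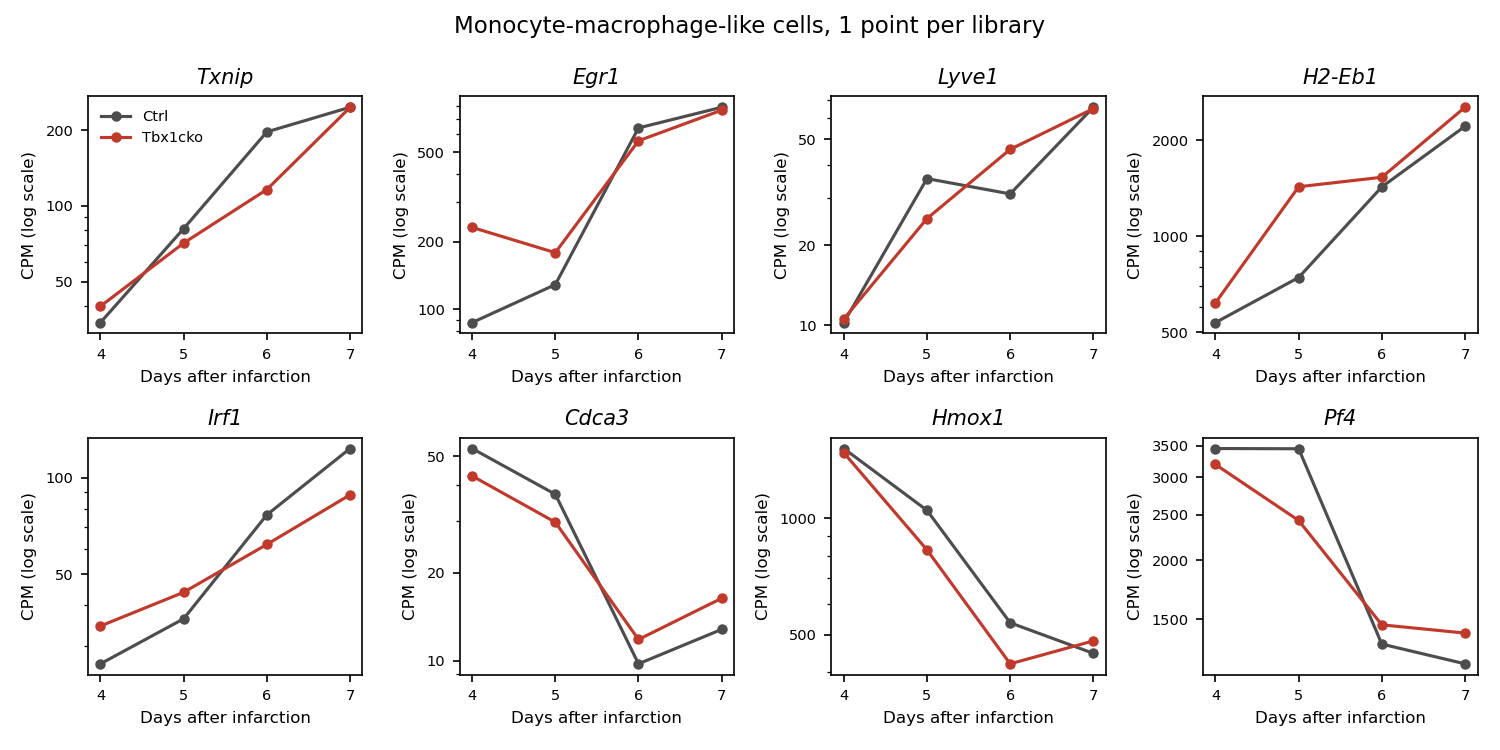
CPM (log axis) of 8 genes in monocyte-macrophage-like cells against day after infarction, with 1 point per library, Ctrl in grey and Tbx1cko in red, joined by lines; there is 1 library per point, so no error bars are drawn. Txnip, Egr1, Lyve1, H2-Eb1 and Irf1 were higher at day 7 than at day 4 in both genotypes (Txnip slope 0.92 per day), and Cdca3, Hmox1 and Pf4 were lower (Hmox1 slope -0.59 per day).

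In endothelial-like cells 1 gene passed for day by edgeR (1996 at an unadjusted p under 0.05; DESeq2 596). Cd276, an immune checkpoint ligand (ENSMUSG00000035914, chromosome 9), fell by 0.75 per day (SE 0.07, adjusted p = 0.0454), from 28.1 and 30.2 CPM at day 4 to 5.25 and 6.03 at day 7 in Ctrl and Tbx1cko. The matrix protease Mmp14 (-0.72, SE 0.09), the galectin Lgals1 (-0.59, SE 0.07) and the basement membrane collagen Col18a1 (-0.53, SE 0.07) missed the threshold at an adjusted p of 0.0650 each. In these cells, Interferon gamma response genes were higher for 20 of 20 (median 0.40; 0 over all genes tested, 14 adjusted over the list alone; adjusted p = 0.492 with an estimated correlation), among them the checkpoint ligand Cd274 (0.54, SE 0.09) and Gbp5 (0.60, SE 0.12). Cell cycle genes were lower for 30 of 30 (median -0.27; 0 over all genes tested, 18 adjusted over the list alone; adjusted p = 0.473 with an estimated correlation), with the replication gene Mcm6 at -0.30 and the mitotic kinase Plk1 at -0.44. MHC class II presentation was higher for 13 of 14 (median 0.45; 0 adjusted over the list alone, adjusted p = 0.567 with an estimated correlation), with Ciita at 0.75 and the peptide loader H2-DMb1 at 0.65. Early response genes were higher for 23 of 27 (median 0.29; 0 over all genes tested, 9 adjusted over the list alone; adjusted p = 0.567 with an estimated correlation), such as Fosb and Zfp36 at 0.54 each. Icam1 (0.19), Vcam1 (0.27) and Ccl21a (-0.58, with no day 4 libraries 0.21) did not pass. edgeR called 0 without day 4 and 0 without day 5 (345 and 1410 at an unadjusted p under 0.05), 1515 without day 6 and 1347 without day 7.

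In mural-like cells Interferon gamma response and adhesion lists were higher with day at the preset correlation (adjusted p = 0.446 and 0.512 with an estimated correlation), and 1 gene passed. Mt3, a metallothionein (ENSMUSG00000031760, chromosome 8), fell by 1.39 per day (SE 0.15, edgeR adjusted p = 0.0201) and was that gene (894 at an unadjusted p under 0.05; DESeq2 70). Interferon gamma response genes were higher for 18 of 18 (median 0.42; 0 over all genes tested, 15 adjusted over the list alone; adjusted p = 0.446 with an estimated correlation), with Cxcl10 (0.85, SE 0.19), Gbp5 (0.72, SE 0.15) and Irf1 (0.60, SE 0.12). Adhesion genes were higher for 14 of 16 (median 0.09; 0 over all genes tested, 3 adjusted over the list alone; adjusted p = 0.512 with an estimated correlation), with Vcam1 at 0.53 (SE 0.08), Icam1 at 0.36 (SE 0.08) and the selectin Sele at 0.76 (SE 0.20). Cell cycle genes were lower for 25 of 27 (median -0.25; 0 over all genes tested, 6 adjusted over the list alone; adjusted p = 0.446 with an estimated correlation), with Cdk1 at -0.56. AA467197, a small mitochondrial gene (-0.52), Akap12, a kinase scaffold (0.40), and Fosb (0.54) did not pass (adjusted p = 0.109 each). Without day 7, Cxcl10 was at -0.038 and Sele at -0.087. The edgeR count was 1 without day 4 (a rising gene, so not Mt3), 0 without day 5 (579 at an unadjusted p under 0.05), 247 without day 6 and 186 without day 7.

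Dendritic-like cells had 11 rising and 0 falling genes by edgeR (694 at an unadjusted p under 0.05 and DESeq2 100). Egr1 rose by 0.94 per day (SE 0.08, adjusted p = 0.000754), with the metallothionein Mt2 (0.94, SE 0.12), the early activation gene Cd69 (0.78, SE 0.10), Txnip (0.65, SE 0.08) and Irf1 (0.63, SE 0.09). All 13 of 13 Interferon gamma response genes were higher (median 0.45; 1 over all genes tested, 8 adjusted over the list alone; adjusted p = 0.446 with an estimated correlation), and Cd274 was at 0.53 (adjusted p = 0.0896). The Mature dendritic program was higher for 16 of 18 (median 0.26; 0 over all genes tested, 2 adjusted over the list alone; adjusted p = 0.472 with an estimated correlation), with the actin bundler Fscn1 at 0.48. The edgeR count was 0 without day 4 (383 at an unadjusted p under 0.05), 2 without day 5, 174 without day 6 and 84 without day 7.

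Neutrophil-like cells, followed at days 4, 5 and 7, had 144 rising and 14 falling genes (DESeq2 178). Gbp2 rose by 1.16 per day (SE 0.12, edgeR adjusted p = 0.00266), followed by Dennd5b, a regulator of vesicle traffic (1.10, SE 0.10), the arrestin-domain gene Arrdc3 (1.01, SE 0.14) and Lyve1 (0.93, SE 0.11). Lyve1, given above as a gene of tissue-resident macrophages, rose by 0.82 per day in monocyte-macrophage-like cells. RNA carried over from those cells was not tested as a source of Lyve1 or of the class II genes below. The platelet chemokine Ppbp (-1.04, SE 0.18), Adora2b (-0.79, SE 0.11), the cytokine subunit Il23a (-0.77, SE 0.14), the fatty acid receptor Gpr84 (-0.72, SE 0.12) and Nt5dc2 (-0.49, SE 0.10) fell. Without day 7, Gbp2 was at 0.51, Arrdc3 at 2.15, Ppbp at -3.29, Il23a at -2.44, Gpr84 at -1.84 and Nt5dc2 at -1.41, and none of these 6 passed. Without day 4, Arrdc3 was at 0.57, and Il23a (0.040), Gpr84 (-0.22) and Nt5dc2 (-0.047) did not pass. Among list members, Interferon gamma response genes were higher for 14 of 14 (median 0.59; 8 rising over all genes tested, 13 adjusted over the list alone; adjusted p = 0.446 with an estimated correlation), with the GTPase Igtp at 0.86 (1.37 without day 4). Type I interferon response genes were higher for 26 of 26 (median 0.33; 5 rising over all genes tested, 20 adjusted over the list alone; adjusted p = 0.472 with an estimated correlation), with Ifit3b at 0.76 and the ubiquitin-like Isg15 at 0.50 (0.057 without day 7). MHC class II presentation was higher for 10 of 10 (median 0.43; 4 rising over all genes tested, 7 adjusted over the list alone; adjusted p = 0.446 with an estimated correlation). The count was 179 without day 4, 450 without day 5 and 1 without day 7.

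Fibroblast-like cells had 71 genes rising and 40 falling (DESeq2 253), with Cell cycle members among those that fell. Eln, the elastin gene, rose by 1.22 per day (SE 0.11, edgeR adjusted p = 0.000785), together with the secreted C1q relative C1qtnf3 (1.30, SE 0.23; 1.99 without day 5), the transcription factor Nfatc2 (1.01, SE 0.21), Arrdc3 (0.92, SE 0.16) and Gm9780 (0.89, SE 0.09). Cell cycle genes were lower for 20 of 20 (median -0.78; 7 falling over all genes tested, 18 adjusted over the list alone; adjusted p = 0.446 with an estimated correlation). Those that fell included Cdca3 (-1.37, SE 0.19), Ube2c (-1.35, SE 0.26), Ccnb2 (-1.25, SE 0.11), the survivin gene Birc5 (-1.17, SE 0.16), Cdk1 (-0.97, SE 0.20) and the centromere histone Cenpa (-0.94, SE 0.15). Fibroblast transcripts were higher for 12 of 12 (median 0.18; 0 over all genes tested, 3 adjusted over the list alone; adjusted p = 0.473 with an estimated correlation), with the matricellular Postn at 0.29 and the proteoglycan Lum at 0.37. The count was 0 without day 4 (447 at an unadjusted p under 0.05), 2 without day 5, 502 without day 6 and 85 without day 7.

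B-like cells, a class that joins B and plasma clusters, had 72 genes rising and 48 falling (DESeq2 195). Jchain, the joining chain of secreted antibodies (3.50 per day, SE 0.64, edgeR adjusted p = 0.0169), the protease inhibitor Slpi (1.46, SE 0.29), the plasma cell chaperone Mzb1 (1.38, SE 0.19), Serpina3g (1.18, SE 0.16) and Pmaip1, a pro-apoptotic BH3 gene (1.06, SE 0.14), rose. Slpi was at 2045 CPM in Ctrl and 295 in Tbx1cko at day 7, at 0.23 per day without day 7 and 2.46 without day 4, and passed in neither. Jchain was at 4737 CPM in Ctrl at day 7 and at 5.84, 0 and 0 at days 4, 5 and 6, against 0, 314 and 3961 in Tbx1cko at days 4, 5 and 6 and 1558 at day 7. Phlda3 and the macrophage gene Spp1 (-1.06 each), Adam8 (-0.96), Prkcdbp (-0.95) and the heme-binding Hebp1 (-0.92) fell. MHC class II presentation was higher for 11 of 12 (median 0.41; 2 rising over all genes tested, H2-DMa at 0.50 and H2-Oa at 0.46, and 11 adjusted over the list alone; adjusted p = 0.446 with an estimated correlation). T-like cells at days 4, 5 and 7 had 32 rising and 3 falling genes (DESeq2 31), with the growth factor Areg (1.27, SE 0.16, adjusted p = 0.0122), the cytokine Il17a (1.15, SE 0.22; -0.64 without day 7), Mt2 (0.83; 1.25 without day 4), Serpina3g (0.81) and Phlda1 (0.77) rising and Gramd3 (-0.45; -0.12 without day 7) and the translation factor Eif5 (-0.42) falling. The Regulatory T program was higher in them for 8 of 8 (median 0.50; 1 over all genes tested, 5 adjusted over the list alone; adjusted p = 0.446 with an estimated correlation), with the costimulatory receptor Tnfrsf9 (0.72) and the transcription factor Ikzf2 (0.75) short of the threshold. Counts in B-like cells were 0 without day 4 and 0 without day 5 (524 and 677 at an unadjusted p under 0.05), 463 without day 6 and 22 without day 7, and in T-like cells 193 without day 4, 115 without day 5 and 0 without day 7 (229 at an unadjusted p under 0.05).

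Of the 185 day tests of lists, 82 passed camera at the preset correlation, 55 higher and 27 lower with day; with an estimated correlation 0 passed (20 at an unadjusted p under 0.05, smallest adjusted p = 0.446) and fry passed 5 (smallest adjusted p = 0.0438), among them Cell cycle in monocyte-macrophage-like and in fibroblast-like cells. Interferon gamma response and Mitochondrially encoded were higher in 8 of 8 classes and MHC class I presentation in 7. Mature dendritic program and Dissociation and early response were higher in 6, MHC class II presentation in 5, and Type I interferon response and fibroblast transcripts in 3. Regulatory T program and erythroid transcripts were higher in 2, and Lymphatic identity and T cell cytotoxicity in 1. Cell cycle and Oxidative phosphorylation were lower in 5 classes, Y-linked in 4, Glycolysis and hypoxia and Fatty acid handling in 3, and Chemokines, Angiogenesis and Notch, and neutrophil transcripts in 1. Reparative macrophage passed in 3 (1 higher, 2 lower), adhesion in 2 (1 higher, 1 lower) and cardiomyocyte transcripts in 2 (1 higher, 1 lower), and Inflammatory activation and Mesenchymal and matrix passed in 0 by camera.

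**Figure D3:**
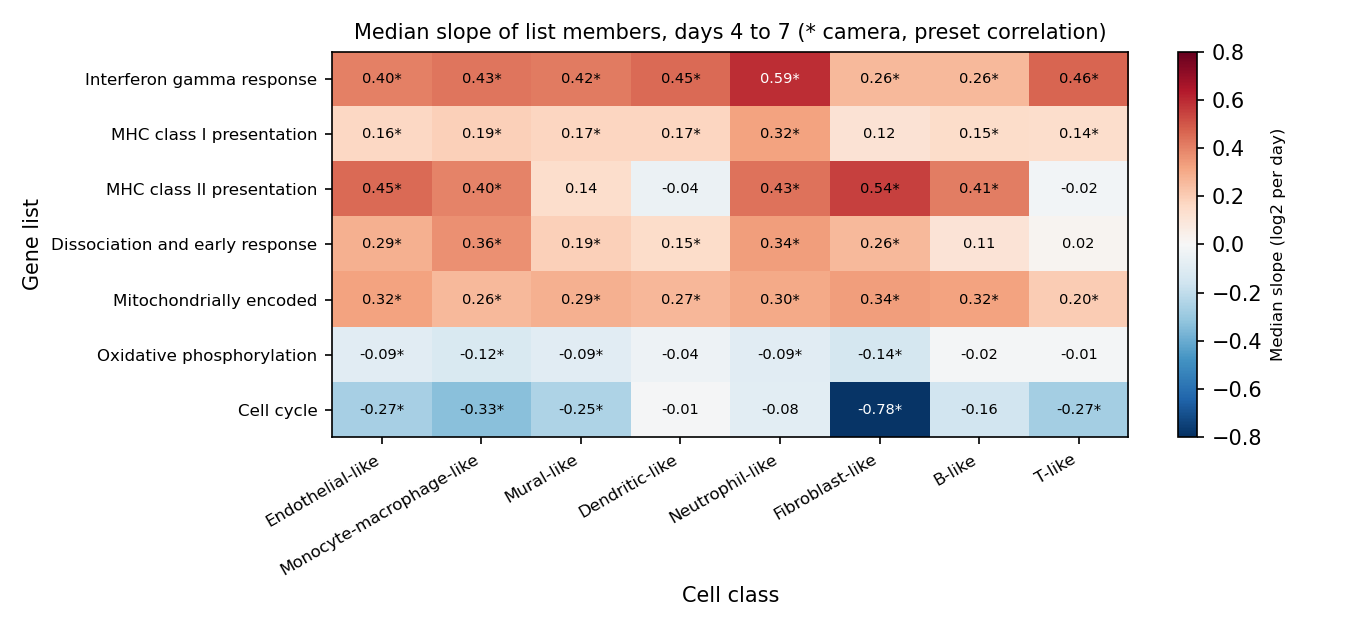
Median log2 slope per day of the members of 7 gene lists (vertical axis) in 8 cell classes (horizontal axis), with the value printed in each cell, colour from blue (lower with day) to red (higher), and an asterisk where camera at the preset correlation passed. Interferon gamma response has an asterisk in 8 of 8 classes, with medians of 0.26 to 0.59, and Cell cycle reaches -0.78 in fibroblast-like cells.

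The fourth comparison asked how cell make-up moved from day 4 to day 7. T-like cells rose from 0.615% to 5.06% of leukocyte-like cells (mean of the genotypes; slope 0.94 per day, SE 0.23, edgeR adjusted p = 0.0228), innate lymphoid type 2-like cells from 0.0125% to 0.329% (1.59, SE 0.37, adjusted p = 0.0228; 0.0656 at a clustering resolution of 2) and immature T-like cells from 0% to 7.07% (4.60, SE 0.62, adjusted p = 0.00241). Of 3998 and 4313 leukocyte-like cells at day 4, 0 were immature T-like, which allows shares of up to 0.0750% and 0.0696%. The innate lymphoid type 2-like share of day 4 rests on 1 cell. B-like cells (0.50, adjusted p = 0.0724; 0.0292 with doublets kept) and monocyte-macrophage-like cells (89.8% to 72.8%, -0.09, adjusted p = 0.620) did not pass. edgeR called 3 of 12 classes, 0 without day 4, 1 without day 5, 6 without day 6 and 0 without day 7; without day 7 the T-like slope was 0.16.

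**Figure D4:**
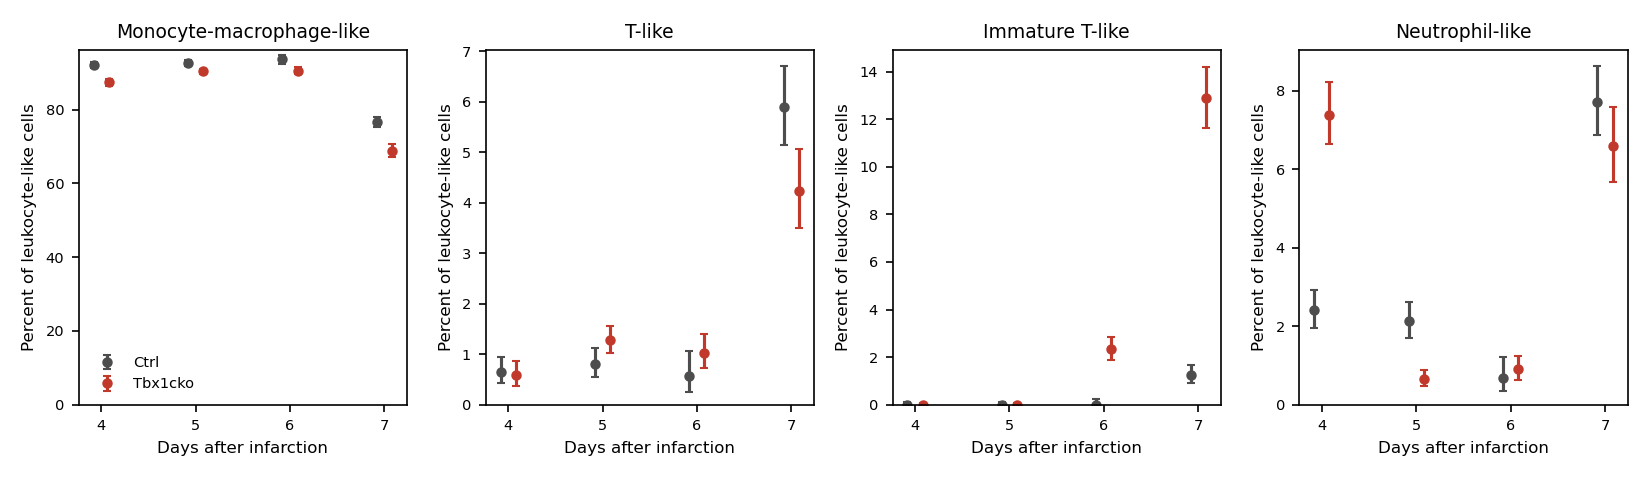
Percent of leukocyte-like cells against day after infarction for 4 classes, with 1 point per library, Ctrl in grey and Tbx1cko in red, and exact binomial 95% intervals as bars. Immature T-like cells reached 12.9% in Tbx1cko and 1.25% in Ctrl at day 7, and T-like cells 4.23% and 5.89%.

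The fifth comparison asked whether the genotype difference moved with day, since the submitters expected early differences. edgeR called 0 genes for the interaction of genotype with day in the 8 classes (372 at an unadjusted p under 0.05), and DESeq2 called 0. Leaving out day 6 or day 7 gave 1 each. This fit has no day block, so the deviation shared by the libraries of a day enters its residual. Its p-values may therefore be too large. At an unadjusted edgeR p under 0.05 there were 30 of 12689 genes in endothelial-like and 31 of 12903 in monocyte-macrophage-like cells, below a share of 0.05. The 0 calls therefore do not show that the genotype difference stayed the same over the days.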

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

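The splits of the samples, the sex test and the test of immature T-like RNA were fixed before their results were seen, and all other tests in this part were chosen after.

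Myt1l RNA was found in endothelial-like cells of each Tbx1cko library, at 2.11, 1.92, 2.49 and 2.32 CPM at days 4, 5, 6 and 7, against 0.0854, 0, 0 and 0.138 in Ctrl; mural-like cells of the same days held 4, 3, 1 and 2 Myt1l UMIs in Tbx1cko and 0 in each Ctrl library, which allows up to 2.45 CPM at day 6. Free RNA spread over all cells is argued against, since endothelial-like cells held 79.1% (72.5% to 84.8%) of the 182 Myt1l UMIs of the Tbx1cko libraries and 24.6% of all their UMIs. The upper limit of the change lay below a log2 of 0.5 for 9 of the 11 expressed genes within 1 Mb (median change 0.035). It was 0.13 for Pxdn, 0.12 for Trappc12 and 0.30 for Rps7. Raised transcription of the neighbourhood by that much is argued against for these 9 except Acp1. The limit of Acp1, 0.476, is a normal approximation, and one allowing for the few degrees of freedom could pass 0.5. Raised transcription stays open for Acp1 and for the weakly expressed Sntg2 (upper limit 1.28) and Sh3yl1 (0.70). Sequence inherited with the genotype, such as a transgene, is a candidate explanation, since 4 of 4 Tbx1cko libraries lay above every Ctrl library. It cannot be told apart from a biological effect of the genotype, because both are present in the same libraries.

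Immature T-like cells numbered 435 in the Tbx1cko libraries and 46 in the Ctrl libraries, with 91 in Tbx1cko at day 6, 344 in Tbx1cko at day 7 and 46 in Ctrl at day 7. These counts depend on naming. Before the filters, cluster 21, with Dntt among its leading genes, held 179, 639 and 64 cells of these libraries. Cluster 26, with Rag1, held 10, 466 and 47, and many of these cells stayed unnamed. Subclusters 13 (76 cells of Tbx1cko at day 6) and 14 (64 at day 7) scored highest as immature T-like yet stayed unnamed. Of kept cells, 4871 of 5341 were named in Tbx1cko at day 7 and 6328 of 6429 in Ctrl. The genotype as the sole cause is argued against by the 46 cells in Ctrl at day 7 and by 0 such cells in Tbx1cko at days 4 and 5, which allows shares of up to 0.0696% and 0.0410%. In Tbx1cko at day 7, 1.74% (0.643% to 3.76%) of the 344 cells had a Y-linked UMI, against 19.6% of the other cells and 8.85% (10 of 113) of the T-like cells of that library (median UMIs 10955 in immature T-like and 8701 in other cells); at day 6, 3.30% (0.685% to 9.33%) of immature T-like and 10.3% of other cells had one (13558 and 7442). Tissue carried over from part of the pooled animals may leave such a difference and stays open as a hypothesis, but the share also differs between cell types. Of their share of leukocyte-like cells, edgeR gave an adjusted p of 0.00241 for day and 0.570 for genotype, the latter 0.0320 over all cells.

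The slopes of the 354 called genes in monocyte-macrophage-like cells run along with sex and with day 6 and day 7 libraries that stood apart. Sex is argued against as the whole cause: within day 5, the female minus male difference in the direction of the slope had a median log2 of 0.10 (quartiles -0.04 to 0.24), against the 1.62 that the slopes give over 3 days. The day 6 libraries alone are argued against, since 335 of the 335 called genes tested without them still passed over all genes. The day 7 libraries alone are argued against for the 114 of 332 called genes tested that passed without them, and stay open for the other 218. A difference in handling between days may still add to the slopes, because each day was collected once, and it cannot be told apart from time after infarction, the biological explanation that the design names. The slopes were also not separated from the shift in the mix of clusters within the class, given above.

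Of 35 splits of the 8 libraries into 4 and 4, 32 could be estimated with day in the fit. For genotype genes the real split called 1 and the highest other split 153, and 32 of the 32 splits gave as many, so chance cannot be excluded. That highest split set Ctrl of day 4 with Tbx1cko of day 5 against the other libraries of those days, and a count that high may come from a structure of the samples, which was not tested. For gene lists the real split passed 76 and the highest other 89, with 15 splits as large, and chance cannot be excluded. For class shares and T subset shares the real count was 0, so that each of the 32 splits is as large by construction and says nothing about chance (highest other 1 and 0). The 8 splits that part both libraries of all 4 days, as the real one does, gave 1 to 16 genes and 73 to 89 lists in the others, and are too few for a share under 0.05.

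Among 282 groups of 4 libraries, 34 (12.1%) held a library far from the other 3 by the 95% limit of Dixon's ratio. The 4 libraries of a group are 4 different days, and many of the values are genes named for a day slope. An extreme first or last day is then built in, so this share cannot be set against a chance rate. The median mitochondrial share of Tbx1cko at day 7 was 8.38%. Monocyte-macrophage-like cells at day 7 were 76.7% of leukocyte-like cells in Ctrl and 68.9% in Tbx1cko. In Ctrl at day 7, T-like cells were 5.89%, NK-like cells 1.53%, innate lymphoid type 2-like cells 0.245% and immature T-like cells 1.25%. Tbx1 in Ctrl at day 6 was at 0.604 CPM in the joined endothelial-like classes. In Tbx1cko at day 7, endothelial-like H2-Q6 was at 294 CPM, Cxcl9 at 310.4 and Gbp5 at 73.8, and in Ctrl at day 7 Cxcl10 was at 233 and Gbp5 at 39.6. Monocyte-macrophage-like Ctla2a was at 45.2 CPM in Tbx1cko at day 7. Mural-like Gbp3 was at 135 CPM, Gbp5 at 67.9 and Cxcl10 at 370.1 in Tbx1cko at day 7, while Gbp5 was at 35.02, Cxcl10 at 274 and Sele at 24.3 in Ctrl at day 7 and Plac8 at 76.2 in Ctrl at day 6. Dendritic-like Hba-a1 was at 21.4 CPM, Mcam at 51.4 and Mgp at 139 in Ctrl at day 6, Mgp at 87.1 in Tbx1cko at day 6 and Mt2 at 1000.1 in Tbx1cko at day 7. Fibroblast-like Hbb-bt was at 71.9 CPM, Hba-a2 at 373 and Nfatc2 at 126 in Tbx1cko at day 7. B-like Jchain was at 4737 CPM, Slpi at 2045, Mzb1 at 1603 and Pmaip1 at 157 in Ctrl at day 7.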

How the results depend on the processing

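The settings with cells up to 20% mitochondrial UMIs, with female-called cells and without immature T-like cells were chosen after the data were seen, as was leaving out each day for Tbx1.

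The genotype gene count was 1 as reported, 11 with DESeq2, 159 with no filter, 4 with stricter cells, 9 in female-called cells and 6 to 16 with each day left out. Without the replicate block, that is without the pairing by day, it was 0 (332 at an unadjusted p under 0.05; DESeq2 was not run for it), and genotype lists went from 76 to 54. The block changed no other call: class shares and T subset shares stayed at 0. The day gene count was 791 as reported, 2821 with DESeq2, 2094 with no filter, 367 with at least 50 cells, where fewer classes were tested, and 373 to 5403 with each day left out. It was 18871 with day as a factor, a test of any difference between days, and 14 in Ctrl alone and 274 in Tbx1cko alone, each with 4 libraries. In female-called cells of days 5 to 7 edgeR called 0 (2048 at an unadjusted p under 0.05), and DESeq2 was not run for it. Of the called genes of monocyte-macrophage-like cells, selected for their slope, 320 of 320 kept their sign there (median slope 0.50 against 0.54). The interaction count was 0 as reported, 31 with no filter, and 0 to 1 with each day left out. List counts fell from 76 to 0 with an estimated correlation and 0 with fry for genotype, and from 82 to 0 and 5 for day. The genotype share count was 1 over all cells, and the day share count of 3 ranged from 0 to 6 with each day left out. Where no construction is named, the cause was not tested.

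Among named genes, Plac8 in mural-like cells was at -0.25 for genotype in female-called cells, and Ccl21a in endothelial-like cells had a day slope of 0.27 there. With each day left out, day slopes ranged from -1.73 to 0.21 for Ccl21a, -2.44 to 0.040 for Il23a in neutrophil-like cells, -0.64 to 1.66 for Il17a in T-like cells, and -0.038 to 1.11 for Cxcl10 and -0.087 to 0.94 for Sele in mural-like cells; the cause was not tested. Further genotype values moved by over 1.5 times, and of these Hba-a2 passed without day 7 and Hba-a1 in dendritic-like cells passed in female-called cells (-1.69). Without day 4, Cxcl1 moved to 0.19 and Tnip3 to 0.21 in monocyte-macrophage-like cells, and Icam1 to 0.065 and Tpx2 to 0.64 in endothelial-like cells. Without day 5, Cd74 moved to 0.24 and H2-Eb1 to 0.17 in monocyte-macrophage-like cells, Icam1 to 0.25, Hbb-bt to -1.20 and Hba-a2 to -1.23 in fibroblast-like cells, Ccl21a to -0.41 in endothelial-like and Ccl2 to 0.25 in mural-like cells. Without day 6, Tpx2 moved to 0.25 and Vcam1 to 0.31 in endothelial-like and Cd74 to 0.098 in dendritic-like cells. Without day 7, Vcam1 moved to 0.034 and H2-Q7 to 0.26 in endothelial-like, Gbp7 to -0.16 in monocyte-macrophage-like and Hba-a2 to -3.29 in fibroblast-like cells. With doublets kept, Ccl2, Cxcl1 and Plac8 in mural-like cells were at 0.13, 0.40 and 0.38, F11r, Ptgs2 and Icam1 in fibroblast-like cells at 0.37, -0.36 and 0.28, and Vpreb3 in B-like cells at -0.61. In female-called cells, Ccl17 was at 2.15 in monocyte-macrophage-like, Cxcl1 at 0.33 and Ifit1 at 1.20 in mural-like, Ccl21a at -0.38 and Vcam1 at 0.29 in endothelial-like, and Hba-a2 at -1.22 in fibroblast-like cells. In stricter cells, Vcam1 was at 0.34 in endothelial-like, Ccl2 at 0.80 in mural-like and H2-Eb1 at 0.23 in monocyte-macrophage-like cells. Among values that moved less, Klf2 in dendritic-like cells passed without day 5 and without day 6, as did Hba-a1 there (-3.53 and -3.09), and Esam and Mcam there passed without day 5. Hbb-bt passed in fibroblast-like cells without day 7 (-2.92) and in neutrophil-like cells without day 4 (-2.78). In cells up to 20% mitochondrial UMIs, Vpreb3 was at -0.60 and endothelial-like Vcam1 at 0.093. Over all alternatives, named genes kept direction and side of the threshold in 633 values for genotype and 865 for day. They lost the call in 5 and 277, gained it in 36 and 78, and reversed in 1 and 6. Tbx1 stayed lower in Tbx1cko in each of these fits. It was at -2.10 without day 4 and -1.22 without day 5, and in lymphatic endothelial-like cells alone at -0.87 over all 4 days and -0.79 over days 4, 5 and 7 with at least 15 cells per library. The Ctrl library of day 6 had the fewest UMIs, 25694848.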

Other observations

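The tests of T-like cells' own RNA were chosen after the result was seen, and the test of immature T-like RNA before.

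Oxidative phosphorylation genes were lower with day in fibroblast-like cells for 30 of 30 (median -0.14, adjusted p = 0.446 with an estimated correlation), in monocyte-macrophage-like cells for 29 of 30 (median -0.12, adjusted p = 0.567 with an estimated correlation) and in endothelial-like cells for 27 of 30 (median -0.09, adjusted p = 0.567 with an estimated correlation). Glycolysis and hypoxia genes in fibroblast-like cells were lower for 15 of 21 (median -0.18), with 3 falling over all genes tested, 6 adjusted over the list alone and adjusted p = 0.446 with an estimated correlation. In B-like cells, Reparative macrophage genes were lower for 19 of 21 (median -0.35; 4 falling over all genes tested, 7 adjusted over the list alone; adjusted p = 0.446 with an estimated correlation). Chemokines were lower there for 14 of 17 (median -0.23; 2 falling over all genes tested, 6 adjusted over the list alone; adjusted p = 0.567 with an estimated correlation), beside Spp1, a gene abundant in macrophages.

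In monocyte-macrophage-like cells the T cell transcripts Cd3d, Cd3e, Cd3g and Tcf7 together had 211 UMIs in Tbx1cko and 74 in Ctrl at days 4 and 5, a ratio per UMI of 2.60 (1.98 to 3.43), and a ratio of 3.43 (2.996 to 3.94) at days 6 and 7. RNA of immature T-like cells is argued against as the whole source, since none were found at days 4 and 5. RNA or doublets of T-like cells stay open as a source: the ratio of what those cells hold was lower for the pooled days at 1.52 (1.37 to 1.69), but at day 4 the intervals meet (1.36 to 2.87 against 0.962 to 1.36). At day 5 they separate (3.46, 2.29 to 5.40, against 1.69, 1.47 to 1.95), but not once the latter is scaled by the barcodes of the 2 libraries, 13598 against 8915, on which doublets depend (2.58, 2.25 to 2.97; at day 4 the scaled ratio is 1.05, 0.885 to 1.25, below that of monocyte-macrophage-like cells). These intervals cover counting error only, and no biological explanation was tested.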
